A study of Mus musculus with 6 samples.

How the data were processed

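RNA of 6 heart tissue samples of male mice was measured on Affymetrix mouse expression arrays, 1 array per sample. Each sample is called a heart here for short. The labels place 3 samples in a wild-type group and 3 in a Cav1 knockout group, and give an age of 5 to 6 months and a fast of 6 hours for all of them. Cav1 encodes caveolin-1, the main coat protein of caveolae, the small flask-shaped pits of the plasma membrane. The labels give neither the strain of the mice nor the part of the gene that was deleted. The sample titles carry distinct numbers, but no label states outright that each sample came from an animal of its own, so p-values measure the spread between these samples.

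Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns, and 2 ug of it was made into biotin-labelled RNA with the Affymetrix One-Cycle kit. GCOS 1.4 is named in the submitters' processing notes, with no role. The deposited table holds 1 intensity on a linear scale for each of 45101 probe sets and each array. How probe sets were summarised, corrected for background and scaled is not given in the sources used here. The lowest deposited intensity per array lay between 5.11 and 5.34 and the highest between 21908 and 22630. Array medians of the deposited intensity ran from 43.9 to 45.8. No pair of arrays was a duplicate: at most 2252 of the 45101 intensities were identical in any pair, and Spearman's correlation across probe sets lay between 0.989 and 0.997. The arrays' 3' to 5' ratio of the beta-actin control probe sets was alike, 0.56 to 0.62 on the log2 scale.

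The rules that follow were set before the data were examined, except where said otherwise. Trimmed means (2% at each end) were to agree within 5% for the table to be used as deposited. They differed by 8.42% between the highest and the lowest array, so the intensities were quantile normalised with limma 3.58.1 in R 4.3.3. This choice turned on wild type replicate 1, with a trimmed mean of 154.61. The other arrays ran from 163.14 to 167.62, inside the limit of 5%. Fold changes are on the scale of log2(intensity + 16), which understates the change of low genes. The 64 control probe sets were left out, and the 22519 of the other 45037 probe sets in the upper 50% by mean over all arrays were tested, the lowest at a mean log2 value of 5.92. Knockout minus wild type was fitted with lmFit and eBayes with a trend, with no covariate, and p was adjusted after Benjamini and Hochberg over the probe sets tested. The threshold was an adjusted p of 0.05, with no limit on the fold. With 3 against 3, the number of arrays limits the precision.

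Names came from the platform annotation of 2016: 34945 probe sets had 1 gene symbol, 932 had several and 9160 were not named, and none was named from a probe set with several symbols. Of those with 1 symbol, 34741 matched a gene of the RefSeq table of assembly GRCm38.p6, and no symbol needed an update. That table served for names and for which genes neighbour each other, and its coordinates are not printed because the array names no build.

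For 44 gene lists, 1 probe set per gene was used, the brightest by mean, which left 11486 genes. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 42 lists that qualified. Some lists share genes: Postn and Cilp are in the matrix and the hypertrophy list, Fabp4 in the endothelial, the fatty acid uptake and the adipocyte list. Col1a1, Col1a2, Col3a1, Loxl1 and Fn1 are in both the fibroblast and the matrix list. Genes within 10 Mb of Cav1 on its chromosome were compared with all other genes by Fisher's exact test, two-sided, without Cav1 and Cav2. Knockouts made in cells of one strain and crossed to another keep donor sequence around the deleted gene, and this test asks about it.

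The genes named are all measured caveola genes, the 15 largest rises and the 15 largest falls among probe sets with 1 symbol, past the threshold and with no overlap between the groups, up to 4 members of each list with the smallest p, all members past the threshold in lists past it, and called genes within 10 Mb of Cav1. Other genes are said to have been chosen after their values were seen.

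The test was tried on simulated data: 20 runs of 3 against 3 arrays over 22519 tested probe sets with the real means and the trend of the real spreads, varying independently of each other, 200 of them changed. Recovered were 26.5% of probe sets changed 1.25-fold, 86.1% at 1.5-fold, 84.5% at 2-fold and 84.1% at 3-fold. Raised probe sets were recovered at 99.0% at 2-fold. Lowered ones were recovered at 74.0% there, because only 74.7% of them stayed above the filter on low values. Of the calls, 4.99% were false, and runs with nothing changed gave 0 calls on average. A list shifted by 0.20 on the log2 scale was called in 100% of runs. Because its genes varied independently, this does not bear on lists whose genes vary together.

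The alternatives were other pseudocounts (1 and 64), no filter and the upper 75% and 25% of probe sets, the intensities as deposited, centring on the median, eBayes without the trend or with a robust one, array weights, each heart left out in turn, a 1.5-fold limit, an adjusted p of 0.1, camera with an estimated correlation, limma's fry, the mean of a gene's probe sets, lists without the genes near Cav1, and windows of 5 and 20 Mb. Added after seeing the data were a fit with the mean of the adipocyte list as a covariate and the lists without the genes of the adipocyte list. The part of the smooth muscle and pericyte list that leaves out genes also used by cardiomyocytes was likewise chosen after the result of the whole list was seen.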

Results

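The data are 6 arrays of mouse heart RNA, 3 from wild-type and 3 from Cav1 knockout hearts, with 22519 probe sets tested. The summed intensity per array ran from 11737000 to 12397000. On the first principal component, which held 50.8% of the variance, the 3 knockout hearts lay at 7.76 or above and the 3 wild-type hearts at -4.64 or below. The second component, with 19.3%, spread the wild-type hearts from -12.6 to 12.4, with wild type replicate 1 apart from the other 2. Across probe sets, wild type replicate 2 had Spearman correlations of 0.995 to 0.996 with the knockout hearts, and of 0.992 and 0.995 with the other wild-type hearts.

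Cav1 itself was measured first, as a check of the labels. Its probe set stood at an intensity of 3968 ± 215 (SD, n = 3) in wild-type hearts and 107 ± 9.85 (SD, n = 3) in knockout hearts, which is 2.69% of the wild-type level or 37.2-fold lower. The single wild-type hearts gave 3852, 3836 and 4216, and the knockout hearts 118, 101 and 101. On the log2 scale the difference was -5.02 (SE 0.067, limma, Benjamini-Hochberg adjusted p = 1.65e-09). Whether this probe set lies in the deleted part of the gene is not given in the sources used here. What remained in knockout hearts lay at percentile 66.1 to 68.9 of all probe sets, and no part of it can be assigned to Cav1 transcript or to background.

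Some other caveola genes rose. Cav2, the partner of caveolin-1, rose by 0.49 on the log2 scale (SE 0.047, limma adjusted p = 0.00146), and 3 genes for cavins and a caveola ATPase rose too: Cavin3 by 0.60 (SE 0.077), Cavin1 by 0.35 (SE 0.051) and Ehd2 by 0.35 (SE 0.075). Of the 12 measured members, 4 rose, 1 fell (Cav1) and 7 did not pass. Adjusted over the list alone, 5 were higher and 2 lower. Muscle caveolin, Cav3, had a log2 fold change of -0.15 and a limma adjusted p of 0.136, and Cavin2 had 0.11 with 0.159. Ror1 stood at 0.12, Pacsin3 at -0.047, Flot1 at 0.015, Flot2 at 0.020 and Cavin4 at -0.0043, all short of the threshold. A weaker probe set of Cav2 had a log2 fold change of 0.059 and did not pass. Cav2 is a neighbour of Cav1 on the chromosome, so donor sequence and genotype cannot be told apart for its rise. As a list, with a median log2 fold change of 0.063 and a mean of -0.26 that Cav1 sets, the caveola genes did not pass camera (Benjamini-Hochberg adjusted p = 0.104). Without the genes near Cav1 it passed as higher at the preset correlation (camera adjusted p = 0.0301), while the whole list had adjusted p = 0.357 with an estimated correlation. Fry called the whole list lower (adjusted p = 0.0126).

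**Figure D1:**
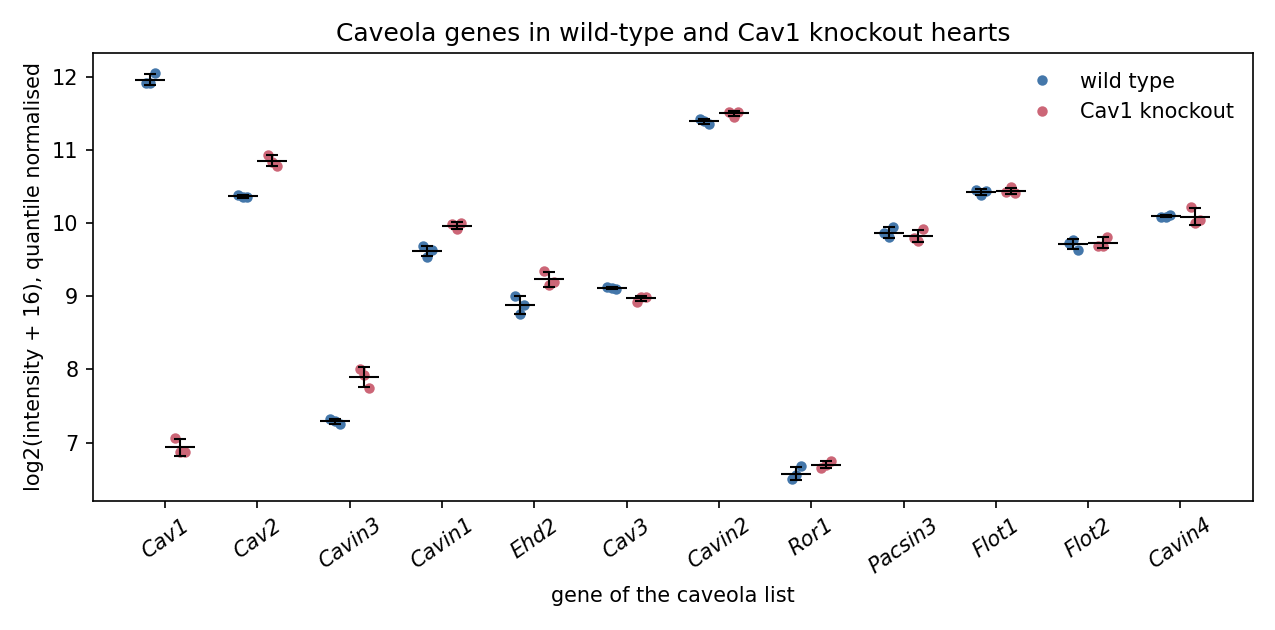
Log2(intensity + 16) after quantile normalisation for the 12 measured caveola genes, with 1 point per heart, bars at the mean and error bars of 1 SD (n = 3 per group). Cav1 fell from a mean of 11.96 to 6.93, and Cav2 rose from 10.36 to 10.85.

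Across the array, more genes rose than fell in knockout hearts. Of the 22519 probe sets tested, 714 passed at an adjusted p of 0.05 (limma, Benjamini-Hochberg), 531 higher and 183 lower in knockout, so that 74.4% of the calls were higher. They cover 385 genes with a higher and 144 with a lower probe set, 527 in all. The split depends on the scaling: with the intensities as deposited 577 were higher and 58 lower, or 90.9% higher. The median log2 fold change of all tested probe sets was -0.0096, and 0.032 as deposited. All 714 called probe sets had groups that did not overlap. The threshold itself favours such groups, so this adds no support to the calls. Over all tested probe sets the share was 26.3%, against 10% by chance. The changes were small: 134 of the calls reached 1.5-fold (116 higher, 18 lower), and the median called change was 1.32-fold. The count was 189 without knockout replicate 1, 227 without knockout replicate 2, 299 without wild type replicate 3 and 470 without wild type replicate 1.

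The largest rise was that of Abhd1, 2.57 on the log2 scale (SE 0.082, limma adjusted p = 1.87e-06), from 6.42 ± 0.079 to 8.99 ± 0.14 (SD, n = 3 each). It was followed by Tspan2, a tetraspanin, at 1.60 (SE 0.062), Osbpl3, a lipid-binding protein, at 1.58 (SE 0.074), and S100a6, a calcium-binding protein, at 1.23 (SE 0.074). Also among the 15 largest rises were Nts at 1.11, Fxyd5 at 1.11, Tspan6 at 1.09, Entpd1 at 1.07, Kcne1 at 1.05, Lyve1 at 1.04, Tes at 1.01 and Ldb2 at 1.00. The wild-type means of Nts, Kcne1 and Ldb2 were 5.81, 5.53 and 5.71. They lay below 5.92, the lowest mean log2 value of the probe sets tested. A brighter probe set of Ldb2 rose by 0.45, past the threshold. Lrrn4 at 1.05 and Alpk3 at 1.01 passed narrowly, with limma adjusted p of 0.0436 and 0.0472. Ppp1cb had 1 probe set at 1.09, while a brighter one of the same gene fell by 0.20, past the threshold too; 2 genes in all had called probe sets in both directions. A weaker probe set of Osbpl3 had a log2 fold change of -0.13 that did not pass. After Cav1 the largest falls were Hddc3 at -2.11 (SE 0.25, with an SD of 0.63 in the 3 wild-type hearts), Sorcs2 at -1.16 (SE 0.080) and Arhgap26 at -1.01 (SE 0.064), whose other 2 tested probe sets stood at -0.22 and 0.14 and did not pass. Igf2, a growth factor, fell by 0.78, Cxcl12, a chemokine, by 0.75, Ide, insulin-degrading enzyme, by 0.65, and Clec3b by 0.65. Man2a2 fell by 0.61, Phlda1 by 0.59, Pkd2l2 by 0.58, Slc36a2 by 0.56, Cyp4b1 by 0.55, and Klhl32 and Slit2 by 0.53 each.

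Many genes of the extracellular matrix rose, and the list passed camera at the preset correlation. Of 39 tested members of that list 17 rose, none fell and 22 did not pass, and adjusted over the list alone 32 were higher. Postn, the matricellular protein periostin, rose by 0.81 (SE 0.051, limma adjusted p = 0.000153), Cilp by 0.84 (SE 0.085), and collagen genes with them: Col5a2 by 0.70, Col4a1 by 0.65, Col3a1 by 0.65, Col18a1 by 0.60, Col14a1 by 0.53, Col1a1 by 0.51, Col6a3 by 0.46, Col4a2 by 0.44, Col6a2 by 0.36 and Col6a1 by 0.34. Bgn, Loxl1, Sparc, Comp and Fmod passed as well, between 0.30 and 0.51. The median log2 fold change of the list was 0.39 (camera, Benjamini-Hochberg adjusted p = 1.4e-21, and adjusted p = 0.268 with an estimated correlation). None of the 17 lists that passed camera did so with an estimated correlation, so each call rests on the preset one.

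The endothelial, macrophage, lymphatic and fibroblast lists also passed as higher, and the smooth muscle and pericyte list did not pass. Of 25 endothelial genes 11 rose, among them Pecam1 by 0.71 (SE 0.061), Cldn5 by 0.72 (SE 0.15), Tek by 0.49 and Tie1 by 0.42, and none fell at the array-wide threshold; adjusted over the list alone 14 were higher and 1 lower. The list's median was 0.21 (camera adjusted p = 5.11e-10, and adjusted p = 0.283 with an estimated correlation). Of 28 macrophage and monocyte genes 8 rose, including Ptprc by 0.75, Laptm5 by 0.54, Mpeg1 by 0.52 and Ctss by 0.46, with 23 higher adjusted over the list alone and a median of 0.29 (camera adjusted p = 2.97e-13, and adjusted p = 0.283 with an estimated correlation). List counts use the brightest probe set of each gene. For Ccr2 and Fcgr1, chosen after their values were seen, it stood at -0.056 and -0.10 and did not pass, while weaker probe sets of both genes rose. Of the 4 tested probe sets of Laptm5, 1 was called. Of 6 lymphatic endothelial genes, Lyve1, Mmrn1 at 0.81 and Flt4 at 0.34 rose, with 4 higher adjusted over the list alone and a median of 0.35 (camera adjusted p = 0.000325, and adjusted p = 0.284 with an estimated correlation). Of 22 fibroblast genes 5 rose (Loxl1, Col1a1, Col3a1, Meox1 and Mfap5) and Clec3b fell. The matrix list also holds Loxl1, Col1a1 and Col3a1, so their rises count in both lists. Adjusted over the fibroblast list alone 10 were higher and 1 lower, with a median of 0.12 (camera adjusted p = 2.18e-05, and adjusted p = 0.284 with an estimated correlation). Of 20 smooth muscle and pericyte genes, Mustn1 rose by 0.49 and Higd1b by 0.37, both also adjusted over the list alone, and the median of 0.0070 did not pass (camera adjusted p = 0.482).

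Some genes of the fetal and hypertrophy list rose. That list holds genes of several cell types, so its rise is no measure of cardiac hypertrophy. Of 30 tested members 6 rose: Vim by 0.79 (SE 0.034, limma adjusted p = 1.49e-05), Myh7, the slow myosin heavy chain, by 0.84 (SE 0.13), Mybpc2 by 0.48, Actn1 by 0.28, and Postn and Cilp, which the matrix list also holds. Adjusted over the list alone 11 were higher and 0 lower, and the median was 0.085 (camera adjusted p = 7.71e-05, and adjusted p = 0.284 with an estimated correlation). Of 31 adult contractile and calcium handling genes 0 passed over all genes and 3 were lower adjusted over the list alone (camera adjusted p = 0.492, median -0.0044). These counts use the brightest probe set of each gene: that of Myom2 had -0.21 and a limma adjusted p of 0.0699, and its other 2 tested probe sets fell by 0.30 and 0.36, past the threshold. When centred on the median the list's median was -0.068 (camera adjusted p = 0.00549 at the preset correlation). As quantile normalised, the list had a camera adjusted p of 0.536 with an estimated correlation. In the TGF beta and BMP list Tgfbr2 rose by 0.31 and Bmp6 by 0.41, 2 of 27, with 3 higher adjusted over the list alone and a median of 0.070 (camera adjusted p = 0.0278, adjusted p = 0.284 with an estimated correlation, 0.0691 with the upper 25% of probe sets and 0.115 without wild type replicate 2). In the hypoxia and angiogenesis list Nos3 rose by 0.50 and Egln3 by 0.42, 2 of 28, with 7 higher and 2 lower adjusted over the list alone and a median of 0.065 (camera adjusted p = 0.0322, adjusted p = 0.284 with an estimated correlation, 0.0666 as deposited, 0.0521 with array weights and 0.0693 without wild type replicate 1).

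Few genes of mitochondrial energy metabolism passed singly, all with small falls, and their 3 lists passed camera as lower at the preset correlation. Of 22 genes of the fatty acid oxidation list, Acacb fell by 0.23 (SE 0.046), Eci1 fell by 0.17 (SE 0.036) and 20 did not pass. The product of Acacb restrains fatty acid oxidation, so its fall does not count as a fall of that pathway. Adjusted over the list alone 11 genes were lower, and the median was -0.087 (camera adjusted p = 1.05e-05, and adjusted p = 0.284 with an estimated correlation). Of 64 genes of oxidative phosphorylation, Cox7a1 fell by 0.14, Uqcr10 by 0.14 and Ndufs4 by 0.19, with 4 lower adjusted over the list alone and a median of -0.036 (camera adjusted p = 4.37e-05, and adjusted p = 0.283 with an estimated correlation). Of 20 genes of the citric acid cycle Dlst fell by 0.16, with 4 lower adjusted over the list alone and a median of -0.058 (camera adjusted p = 0.000259, and adjusted p = 0.305 with an estimated correlation). That list also did not pass with fry (adjusted p = 0.0537) or with the adipocyte covariate, added after seeing the data. Uqcr10, Ndufs4 and Dlst were each called at 1 of 3 tested probe sets, and another of Ndufs4 stood at 0.030. With the intensities as deposited, Acacb, Eci1, Ndufs4, Uqcr10 and Dlst did not pass, at limma adjusted p of 0.125, 0.082, 0.149, 0.0629 and 0.109, and Uqcr10 did not pass with median centring either, at 0.0544.

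Few triglyceride genes and fat markers passed singly, and both lists passed camera as lower at the preset correlation. Of 25 tested triglyceride genes, Pnpla2, the first lipase of triglyceride breakdown, fell by 0.29 (SE 0.045, limma adjusted p = 0.0125), Dgat2, which makes triglyceride, by 0.25 (SE 0.044) and Agpat3 by 0.29 (SE 0.059), 22 did not pass, and 5 were lower adjusted over the list alone. The median was -0.13 (camera adjusted p = 0.00126, and adjusted p = 0.284 with an estimated correlation). With the intensities as deposited these 3 genes did not pass, at limma adjusted p of 0.067, 0.0599 and 0.117. Of the 4 tested probe sets of Agpat3, 1 was called. The adipocyte list had a median of -0.27 (camera adjusted p = 0.00245, and adjusted p = 0.357 with an estimated correlation). Of its 14 tested members Slc36a2 fell and Fabp4, which the endothelial list also holds, rose by 0.15, called at 1 of its 4 tested probe sets. Adjusted over the list alone 1 was higher and 7 lower. Its members varied between hearts of 1 group: Pck1 stood at 6.58, 7.99 and 8.65 in the wild-type hearts and at 5.92, 5.91 and 6.65 in the knockout hearts (log2 fold change -1.58, limma adjusted p = 0.098). The mean of the list per heart, relative to all hearts, was -0.063, 0.34 and 0.74 in wild type and -0.48, -0.54 and -0.0021 in knockout.

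**Figure D2:**
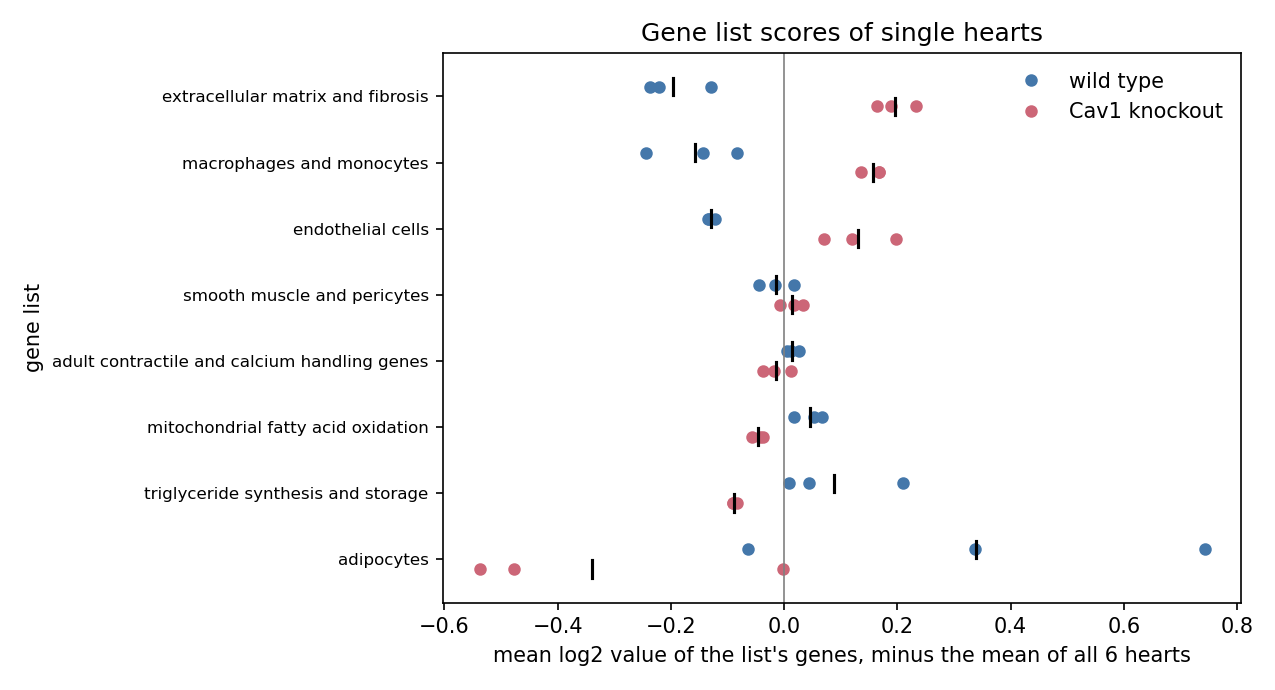
Mean log2 value of the tested genes of 8 lists in each heart, minus the mean of all 6 hearts, with 1 point per heart and a bar at the group mean (n = 3). The matrix score lay between 0.16 and 0.23 in knockout and between -0.24 and -0.13 in wild-type hearts, while the adipocyte scores of the groups overlapped.

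Some control lists passed camera too, at the preset correlation. Of 12 housekeeping genes Actb rose by 0.28 at its brightest probe set (another stood at -0.13 and did not pass) and Eef1a1 by 0.17, with 4 higher adjusted over the list alone and a median of 0.11 (camera adjusted p = 0.00507, and adjusted p = 0.283 with an estimated correlation); centred on the median, the list and both genes did not pass (camera adjusted p = 0.078 for the list, limma adjusted p = 0.078 for Actb and 0.258 for Eef1a1). None of 24 ribosomal protein genes passed, over all genes or adjusted over the list alone, and the median of 0.039 (camera adjusted p = 0.00978, and adjusted p = 0.356 with an estimated correlation) turned to -0.021 when centred on the median (camera adjusted p = 0.986). The ribosomal list also did not pass as deposited, at 0.0778, or without knockout replicate 3, at 0.083. The heat shock list had 0 of 31 passing over all genes or adjusted over the list alone and a median of 0.057 (camera adjusted p = 0.00472, and adjusted p = 0.284 with an estimated correlation). It did not pass with median centring (camera adjusted p = 0.0602), with fry (adjusted p = 0.0867) or with the adipocyte covariate, added after seeing the data. At weaker probe sets Hspa1b rose by 0.68 (limma adjusted p = 0.0409) and Hspb7, chosen after its values were seen, by 0.16 (limma adjusted p = 0.0247), while their brightest ones did not pass. The atrial list, also with 0 of 16 by either count and a median of -0.15 (camera adjusted p = 0.0322, and adjusted p = 0.536 with an estimated correlation), did not pass without wild type replicate 1, wild type replicate 3 or knockout replicate 2, at 0.091, 0.119 and 0.19, or with the mean of a gene's probe sets, at 0.066.

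**Figure D3:**
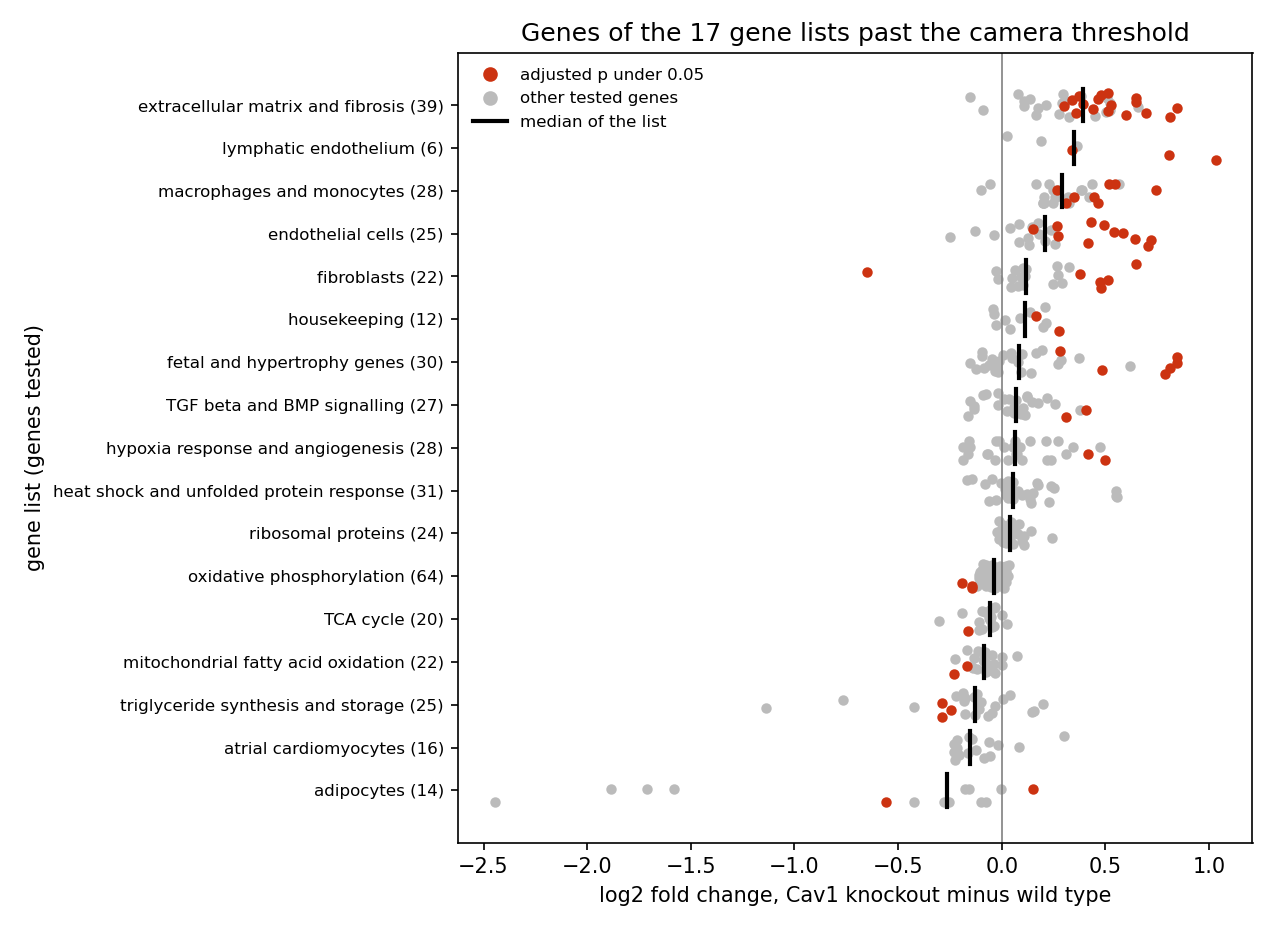
Log2 fold change, knockout minus wild type, of each tested gene of the 17 lists past the camera threshold, with the number of genes tested in brackets. Red points are genes past an adjusted p of 0.05 and black bars the list medians, from 0.39 for the matrix list to -0.27 for the adipocyte list; the ribosomal median was 0.039 here and -0.021 with median centring.

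For genes around Cav1 the test did not pass, and its result depended on the setting. Of 35 tested genes within 10 Mb of it, 3 were called, against 519 of 11419 elsewhere (odds ratio 1.97, 95% interval 0.385 to 6.33, Fisher's exact test, two-sided, p = 0.213). The 3 were Tes at 1.01, Met, a growth factor receptor, at 0.87 (SE 0.075) and Mdfic at 0.30 (SE 0.052), all higher in knockout. The wild-type mean of Met, 5.53, lay below 5.92, the lowest mean log2 value of the probe sets tested. Another probe set of Met was too low to be tested and stood at 0.12. With the upper 75% of probe sets the odds ratio was 3.07 (p = 0.0498, Fisher's exact test), and with a window of 20 Mb 2.38 (p = 0.0146, Fisher's exact test). It was 3.94 with a window of 5 Mb (p = 0.053), 3.53 without the trend (p = 0.0619) and 3.00 with no filter (p = 0.0513), all by Fisher's exact test, and 1.65 to 3.15 with single hearts left out, the highest without wild type replicate 3. It was lower with array weights, 1.18 (p = 0.742, Fisher's exact test), with the upper 25% of probe sets, 1.24 (p = 0.678, Fisher's exact test), and with the adipocyte covariate, added after seeing the data, where no gene in the window was called.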

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

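Control probe sets of the array lay outside the comparisons, and 4 of 64 were higher and 1 was lower in knockout hearts at an adjusted p under the threshold over the controls (limma, Benjamini-Hochberg). The 3 beta-actin probe sets had log2 fold changes of 0.21 for the 3' end, 0.21 for the 5' end and 0.22 for the middle, higher in 3 of 3 knockout hearts than in every wild-type heart, and the brighter of the 2 tested gene probe sets of Actb rose by 0.28, while the other stood at -0.13 and did not pass. The transferrin receptor 5' probe set stood at 0.17, with values in every heart below 5.92, the lowest mean log2 value of the probe sets tested. Actb did not pass with centring on the median. In the other direction, the pyruvate carboxylase 3' control probe set fell by 0.31 (limma adjusted p over the controls = 0.022), lower in 3 of 3 knockout hearts than in every wild-type heart, and the other 3 pyruvate carboxylase controls stood at -0.15, -0.24 and -0.30 and did not pass.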

How the results depend on the processing

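Cav1 passed under every alternative run, with log2 fold changes of -5.21 to -4.56. The counts of calls moved more. Against 714 called probe sets (531 higher, 183 lower), eBayes without the trend gave 411 (338 higher, 73 lower), array weights 1171 with 394 lower, the 1.5-fold limit 134 (116 higher, 18 lower), and an adjusted p of 0.1 gave 1389 (900 higher, 489 lower). Lower calls numbered 103 with no filter and 58 as deposited. The adipocyte covariate, added after seeing the data, left 33 (27 higher, 6 lower); it uses 1 more term for 6 hearts. Leaving out single hearts gave 189 to 749 calls, 154 to 552 higher and 35 to 197 lower: 189 without knockout replicate 1, 227 without knockout replicate 2, 299 without wild type replicate 3 and 470 without wild type replicate 1. Of the 189, 186 were among the 714, but of 749 without wild type replicate 2 471 were, and of 556 without knockout replicate 3 422. Of the 110 called probe sets under the rule for named genes, Cav1 aside, 98 lost their call with the covariate, 50 without wild type replicate 3, 41 without the trend, 34 without wild type replicate 1 and 31 with no filter, as did 62 of 109 without knockout replicate 1 and 55 of 108 without knockout replicate 2. Of 42 lists 17 passed, 0 with an estimated correlation, where the smallest adjusted p was 0.268, and 11 with fry, which does not compare a list with other genes and did not call the fibroblast, citric acid cycle, triglyceride, adipocyte, atrial, TGF beta, heat shock and ribosomal lists. The adipocyte covariate ended the calls of the citric acid cycle, TGF beta, heat shock and atrial lists. The direction turned for the adipocyte list with its own score as a covariate (median -0.0046, as built in) and for the caveola list with fry (median 0.063), where Cav1 weighs most. The odds ratio around Cav1 passed at 3.07 with the upper 75% of probe sets and at 2.38 with a window of 20 Mb. For the other changes the cause was not tested. The matrix, endothelial, macrophage, lymphatic, hypertrophy, fatty acid oxidation and oxidative phosphorylation lists passed under each alternative that could be run except the estimated correlation. Leaving out single hearts moved no list past the threshold in the opposite direction.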

Other observations

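Several lists outside the groups described so far did not pass camera, though single members did. In the cardiac ion channel list Kcnip2, a subunit of the transient outward potassium channel, fell by 0.43 (SE 0.059, limma adjusted p = 0.00728) and Kcne1 rose, while the list's median was -0.053 (camera adjusted p = 0.466). In the nitric oxide and vascular tone list Nos3, endothelial nitric oxide synthase, rose by 0.50, Ramp2 by 0.45 and Ece1 by 0.40, and Agtr1a fell by 0.31 (median 0.068, camera adjusted p = 0.0523). That list lay near the threshold: it passed as higher under 8 of 15 alternatives, among them fry at 0.0126, and in 1 of 6 fits with a heart left out, and had adjusted p = 0.284 with an estimated correlation. In the list of fatty acid uptake Fabp5 rose by 0.38 and Fabp4 by 0.15 (median 0.0010, camera adjusted p = 0.513). Single members passed in further lists: Pex11a fell by 0.29 among PPAR alpha targets (median -0.080, adjusted p = 0.104), Pdk2 by 0.22 in glycolysis (-0.040, 0.108), Gstm1 by 0.20 in oxidative stress (0.0096, 0.95), Irf8 and Oasl2 rose by 0.47 and 0.34 in the interferon list (0.048, 0.0922), and Klf10 rose by 0.57 as Dusp1 fell by 0.38 among immediate early genes (0.079, 0.492). Cxcl12 was the called member of acute inflammation (0.11, 0.0922), Met of ERK signalling (-0.016, 0.95), Lrrn4 and Prnp of nerve, Schwann and mesothelial cells (0.14, 0.104), Kcnip2 of ventricular cardiomyocytes (-0.033, 0.091), and Tnnt1, which fell by 0.42, and Mybpc2, which rose by 0.48, of skeletal muscle (-0.0054, 0.811). The interferon list varied with single hearts: it passed as higher in 3 of 6 fits with a heart left out (camera adjusted p = 0.00493 without knockout replicate 2) and under 4 of 15 alternatives. Without knockout replicate 3 its median was -0.024 (camera adjusted p = 0.956). With all hearts and an estimated correlation it had a camera adjusted p of 0.631. In each pair the first number is the list's median log2 fold change and the second its camera adjusted p. Adjusted over the list alone, 1 ion channel gene was higher and 2 lower, with 4 and 2 for nitric oxide and vascular tone, 3 and 2 for fatty acid uptake, 0 and 2 for PPAR alpha targets, and 2 and 3 for glycolysis. The same counts were 0 and 1 for oxidative stress, 2 and 0 for interferon, 1 and 1 for immediate early genes, 2 and 1 for acute inflammation, and 1 and 1 for ERK signalling. They were 3 and 2 for nerve, Schwann and mesothelial cells, 0 and 2 for ventricular cells, and 2 and 1 for skeletal muscle. Camera ranked the skeletal muscle and ERK lists toward higher although their medians were negative, and the ion channel list had a mean of 0.00030 against its negative median.

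In 8 further lists no gene passed over all genes at its brightest probe set: mitochondrial biogenesis regulators (median -0.060, camera adjusted p = 0.103), the circadian clock (-0.15, 0.0717), proliferation (0.070, 0.0922), lymphocytes (0.063, 0.492), granulocytes and mast cells (0.27, 0.166), red blood cells and platelets (-0.092, 0.327), insulin signalling (-0.017, 0.811) and cholesterol synthesis (-0.038, 0.676). The clock list rested on single hearts: its mean per heart was -0.26 in knockout replicate 1 and 0.084 in knockout replicate 3, and camera gave an adjusted p of 0.301 without the former and 0.00066 without the latter. At weaker probe sets Fdft1, of cholesterol synthesis, fell by 0.41 (limma adjusted p = 0.0287) and Ccnd1, of proliferation, rose by 0.30 (limma adjusted p = 0.0469). Mpped2, of ventricular cardiomyocytes, fell by 0.39 at a weaker probe set (limma adjusted p = 0.0247) and did not pass at its brightest. The glucocorticoid and fasting list had no called gene either (-0.045, 0.745, with a mean of 0.014). Adjusted over the list alone, 2 biogenesis regulators and 2 glucocorticoid genes were lower, insulin signalling and cholesterol synthesis had 1 higher and 1 lower each, and the other 5 lists had 0. Too few genes were tested for a test of the lung, airway and thymus list (2 genes, Sftpb at -0.22 and Ager at -0.077) and the sex check (3). Among the latter, the Y-linked genes Eif2s3y, Uty and Kdm5d had log2 fold changes of -0.094, 0.028 and -0.0035.

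The tests from here on were chosen after the result they bear on was seen. Exceptions are the splits of the hearts and the fits with single hearts left out, which were set beforehand. The calls as a whole: the real split of the 6 hearts gave 714 probe sets and the highest of the other 9 splits gave 0, and 1 of the 10 splits reached the real count. With 10 splits the share cannot go below 0.1, so it is too coarse for a threshold of 0.05.

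The rise of the endothelial, matrix and macrophage lists could come from a lower share of cardiomyocyte RNA, which would raise the markers of every other cell type alike. Knockout minus wild type, the mean of these 3 lists differed by 0.332 (SE 0.025, 92 genes), and that of the 20 smooth muscle and pericyte genes by 0.029 (SE 0.022). The difference was 0.303 (SE 0.046), and 0.316 (SE 0.056) against the 13 genes of the list that cardiomyocytes do not share. Such differences go against a lower share as the whole cause only if smooth muscle cells and pericytes did not fall themselves. That was not tested, and the lists were compared after their results were seen. The adult contractile list differed by -0.029 (SE 0.016, 31 genes). Without wild type replicate 1, whose array had the lowest weight (0.399), the median log2 fold change over the 3 lists was 0.348 and all 3 lists were called. Its matrix and endothelial scores, -0.13 and -0.12, were the closest to knockout among the wild-type hearts. Its macrophage score, -0.14, lay between the others. Leaving it out could therefore hardly shrink the difference. A lower share of cardiomyocyte RNA stays open. So do a change in the number of cells that express the 3 lists, a change within them, and the untested effect of the genotype itself.

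The lower triglyceride list might reflect fat attached to some wild-type hearts, since wild type replicate 3 had both the highest adipocyte score and the highest triglyceride score, 0.74 and 0.21. With the adipocyte score as a covariate the list's median was -0.123 against -0.127. It still passed camera at the preset correlation (adjusted p = 0.0115). The score also holds Fabp4, which rose, and it was mostly lower in knockout hearts. So this fit cannot tell how much of the list's fall came from carried-over fat. Without the genes that the adipocyte list also holds it passed as well (camera adjusted p = 0.00245). That removal leaves in other genes that fat may express, so it does not weigh against carried-over fat. With single hearts left out camera gave the list adjusted p of 0.000266 to 0.0131. Pnpla2, Dgat2 and Agpat3 lost their calls with the covariate. Their log2 fold changes there were -0.27 (SE 0.0728, limma adjusted p = 0.241), -0.15 (SE 0.0573, limma adjusted p = 0.347) and -0.30 (SE 0.0955, limma adjusted p = 0.301). Before, they were -0.29 (SE 0.045), -0.25 (SE 0.044) and -0.29 (SE 0.059). The standard errors grew, and the fold change of Dgat2 shrank too. A part from fat stays open for the list and for these genes. For the adipocyte list itself, no test here separates carried-over fat from genotype.

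Called genes such as Hddc3, Man2a2, Alpk3 and Homer2, the last chosen after its value was seen, lie within 2 Mb of each other in GRCm38.p6, which could reflect donor strain sequence at other loci. Abhd1, the largest rise, and Ppp1cb likewise lie within 2 Mb of each other. Of 522 called genes 345 had another called gene within 2 Mb, against a mean of 358 in 1000 random draws (permutation p = 0.866, one-sided). Of 98 genes changed at least 1.5-fold, 22 had another such gene, pairs with the same first 3 letters left out, against 23.8 (permutation p = 0.654, one-sided). Neither decides the matter: a few loci would not show in a count over the genome, and the strain is not given in the labels, so donor sequence and genotype cannot be told apart for these genes.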
